A study of Mus musculus with 8 samples.

How the data were processed

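RNA sequencing of hepatocytes from wild-type mice (4 libraries) and from mice with a hepatocyte-specific conditional knockout of Taf2 (4 libraries) was analysed. Per the labels' protocols, total RNA was extracted with a QIAGEN miRNeasy kit, libraries were made with an Illumina TruSeq RNA kit and each was sequenced in 2 rounds on a HiSeq3000. The authors deposited estimated counts per gene, which RSEM made on genome build mm10, per the submitters' processing notes. The version of RSEM, the aligner, trimming, and whether strand was used are not given in the sources used here. The deposited table lists 24411 gene symbols, each with its RefSeq transcripts, and its expected counts were not scaled between libraries. RSEM divides reads that match several genes among them, so 2.85% of the values were not whole, and 710 of the genes tested held such values. Values of gene families and pseudogenes with near-identical copies are therefore uncertain. Without a known strand setting, reads of overlapping antisense genes may also be counted together.

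Samples were assigned to genotypes from their titles and genotype labels. The 8 columns whose names match the library names in the sample descriptions were used. A further 8 columns match no sample and were not used in any step. Whether these columns and the ones used stand for the 2 rounds of sequencing is not given in the sources used here.

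Expected counts were rounded to whole numbers. Library totals ran from 18947059 to 23933589, and their effect on the counts of calls was tested by thinning every library to the smallest total. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15, genotype as the group), which left 12122 genes. Libraries were scaled by TMM and compared with edgeR's quasi-likelihood test, knockout against wild type with no other term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values use TMM-scaled library sizes. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Replicates were compared before averaging. Every pair of libraries within a genotype differed by more than sampling noise, with a chi-square per degree of freedom between 3.19 and 8.66. Each library was counted as 1 replicate, although this comparison cannot show that the libraries came from separate animals or cultures. Correlations of log2 CPM were 0.9936 to 0.9954 within genotypes and 0.9585 to 0.9664 between them across genes, which are not independent replicates. The first principal component took 81% of the variance and separated the genotypes. The biological coefficient of variation, as edgeR names the spread beyond counting noise, was 4.57%, and that spread may be technical.

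The 57 gene lists (pathways, complexes and cell markers, with 1553 entries, of which 20 matched no gene symbol in the table and 7 matched under another symbol) were compiled from general knowledge before the data were examined, as were the tests, the rule for named genes and all but 1 of the alternatives. Lists with at least 5 tested members, 53 in all, were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided and adjusted over the lists. Camera was repeated with a correlation estimated for each list. The fry test, which asks whether the genes of a set move one way on balance and does not compare them with other genes, was an alternative.

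Genes named in the text follow a rule. They are Taf2, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, no overlap between the genotypes and a symbol that is not a predicted-gene model, and, for lists described, up to 3 called members with the smallest adjusted p in each direction and the member with the highest mean CPM. This was narrowed in use to 3 members of the direction with more calls and 1 of the other. Of the genes so taken, 2 are not reported here. Others (Ifit2, Acta2, Tm7sf2, Ptprc, Mmp8, Hdc, Alas2, Bpgm, and genes of the closing section that no part of the rule takes) were named after their values were seen. Of 135 genes taken by the rule 130 passed, the largest adjusted p among those being 0.00338. Gene coordinates come from an annotation of the same build and were matched for 12097 of the tested genes.

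The fit was tested on simulated data with the real libraries' means and sizes, in which 200 of 12020 genes were changed. It recovered 67.2% of the genes changed 1.25-fold, 76.1% of those changed 1.5-fold and 95.5% of those changed 2-fold, with 10 false calls. A list raised by 0.5 on the log2 scale was found and 0 of the other lists were called. Each gene was drawn independently in these simulations, so they do not test the list calls where genes vary together. The share of genes changed was also far below the 61.4% called in the real data. Scaling and false calls at that share were therefore not tested.

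Alternatives were RLE and upper-quartile scaling, DESeq2's Wald test, limma-voom with quality weights, no low-count filter (at least 1 count in any library), a stricter filter (1 CPM in at least 4 libraries), a replicate block, thinning, leaving out each library in turn, a log2 change of at least 1, fry, an estimated correlation, and camera on ranks. For gene lists, the DESeq2 and limma-voom alternatives were camera on log2 CPM. The former used DESeq2's size factors, and the latter used voom's values without the quality weights. The alternative that removes members shared with the cell marker lists was added after seeing the data.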

Results

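Gene expression was measured by RNA sequencing in hepatocytes, the main parenchymal cells of the liver, isolated from wild-type mice and from mice with a hepatocyte-specific conditional knockout of Taf2, and harvested 2 days after plating. Taf2 encodes a TBP-associated factor of TFIID, the complex that binds core promoters and recruits RNA polymerase II. The series held 8 libraries, 4 of each genotype. Estimated counts summed to between 18947059 and 22824568 per wild-type library and between 20287023 and 23933589 per knockout library. Between 14246 and 14436 genes were detected per wild-type library and between 14714 and 14855 per knockout library. Transcripts of Alb, which encodes serum albumin, took 3.66% to 4.03% of the counts in the wild-type libraries and 5.22% to 5.86% in the knockout libraries. Levels below are counts normalised to library size (CPM), given as the mean ± SD of 4 libraries per genotype. Each fold change is on the log2 scale with a standard error (SE). The SE was derived from the edgeR test, as the absolute log2 fold change divided by the square root of the test's F statistic.

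Taf2 itself, on chromosome 15 from 55015129 to 55072187 (build mm10), fell from 44.04 ± 2.05 to 13.9 ± 1.26 CPM (SD, n = 4 each; log2 fold change -1.66, SE 0.061; edgeR adjusted p = 9.03e-15). The knockout level was 31.7% of the wild-type level. Each wild-type library held between 865 and 979 Taf2 counts and each knockout library between 269 and 329, so the 2 genotypes did not overlap and every library matched its label. An exact two-sided permutation test of the 4 against 4 values gave p = 0.029, the smallest this design allows. The count covers the whole gene, and the part of it that was deleted is not given in the sources used here.

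The comparison of the genotypes addressed which transcripts differ in hepatocytes of the Taf2 knockout. Interferon-stimulated genes (39 of 41 higher, median log2 fold change 1.86), markers of macrophages (17 of 18, median 2.47) and endothelial cells (17 of 18, median 1.65), and glycolytic enzymes (16 of 18, median 0.80) were higher in the knockout cultures. Enzymes of cholesterol synthesis (24 of 25 lower, median -0.55) and many cytoskeletal genes (26 of 40 lower, median -0.23) were lower. Of these lists only the macrophage and endothelial markers also passed with an estimated correlation between genes (camera adjusted p = 0.0282 each). Of 12122 genes tested, 3663 (30.2%) were higher and 3784 (31.2%) were lower at an edgeR adjusted p under 0.05, with a median absolute log2 change of 0.36 among them. Changes of at least 1 on the log2 scale were uneven, with 836 genes higher and 315 lower.

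**Figure D1:**
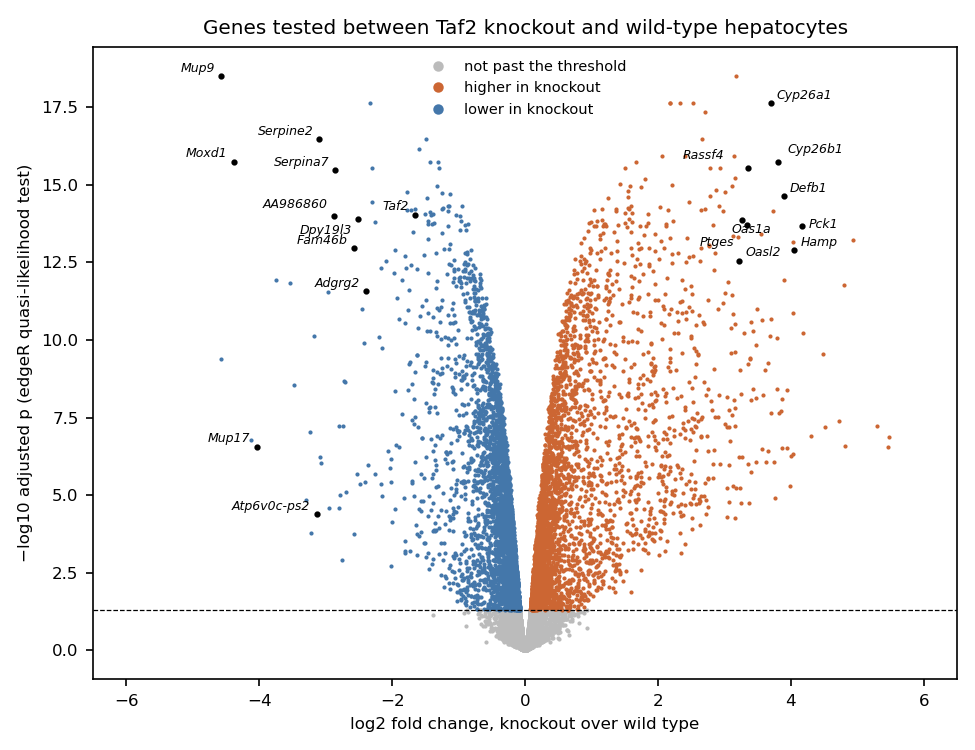
Log2 fold change of each tested gene in Taf2 knockout over wild-type hepatocytes (horizontal axis) against −log10 of its edgeR adjusted p (vertical axis), with 1 point per gene and the dashed line at an adjusted p of 0.05. Named in black are Taf2, at a log2 fold change of -1.66, and genes with the largest changes among those with a mean of at least 5 CPM, from Mup9 at -4.58 to Pck1 at 4.17.

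Among genes with a mean of at least 5 CPM, Pck1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, had the largest rise, from 1.59 ± 0.177 to 28.5 ± 6.32 CPM (log2 fold change 4.17, SE 0.16). Hamp, which encodes the iron hormone hepcidin, rose by 4.05 (SE 0.18), and the antimicrobial peptide gene Defb1 by 3.89 (SE 0.13). Both genes for retinoic acid hydroxylases in this group rose, Cyp26a1 from 4.55 ± 0.670 to 58.8 ± 3.99 CPM and Cyp26b1 from 1.38 ± 0.150 to 19.3 ± 1.56 CPM. Rassf4 rose by 3.35 (SE 0.10) and the prostaglandin E synthase gene Ptges by 3.35 (SE 0.13). The oligoadenylate synthetase family genes Oas1a and Oasl2 rose by 3.27 and 3.22. Values of Oas1a in 7 libraries and of Hamp in 3 were not whole, so part of their reads was shared with other genes.

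The largest falls among genes at this level were in Mup9, a major urinary protein gene that shares reads with near-identical copies, from 59.8 ± 3.84 to 2.52 ± 0.354 CPM (log2 fold change -4.58, SE 0.080), and in Moxd1, from 19.8 ± 1.81 to 0.948 ± 0.207 CPM. The protease inhibitor gene Serpine2 fell from 33.3 ± 1.22 to 3.90 ± 0.484 CPM, and Serpina7, which encodes thyroxine-binding globulin, from 49.5 ± 4.19 to 6.87 ± 1.05 CPM. AA986860, Fam46b, Dpy19l3 and Adgrg2 had log2 fold changes of -2.88, -2.57, -2.51 and -2.40. The falls of Mup17 (-4.04, SE 0.47) and of the pseudogene Atp6v0c-ps2 (-3.14, SE 0.54) were uncertain. Both share such reads as well, and Atp6v0c-ps2 ranged from 12.8 to 43.7 CPM between wild-type libraries. Both also had 0 CPM in some knockout libraries, Mup17 in all but replicate 1. With limma-voom their log2 fold changes were -6.63 and -6.84, and without knockout replicate 1 that of Mup17 was -11.06. DESeq2 did not call Mup17 or Atp6v0c-ps2, at adjusted p = 0.0871 and 0.135, the highest over their alternatives, against lowest values of 1.11e-16 and 1.59e-11. Across the 20 genes with the largest rises and falls at this level the largest edgeR adjusted p was 4.08e-05.

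**Figure D2:**
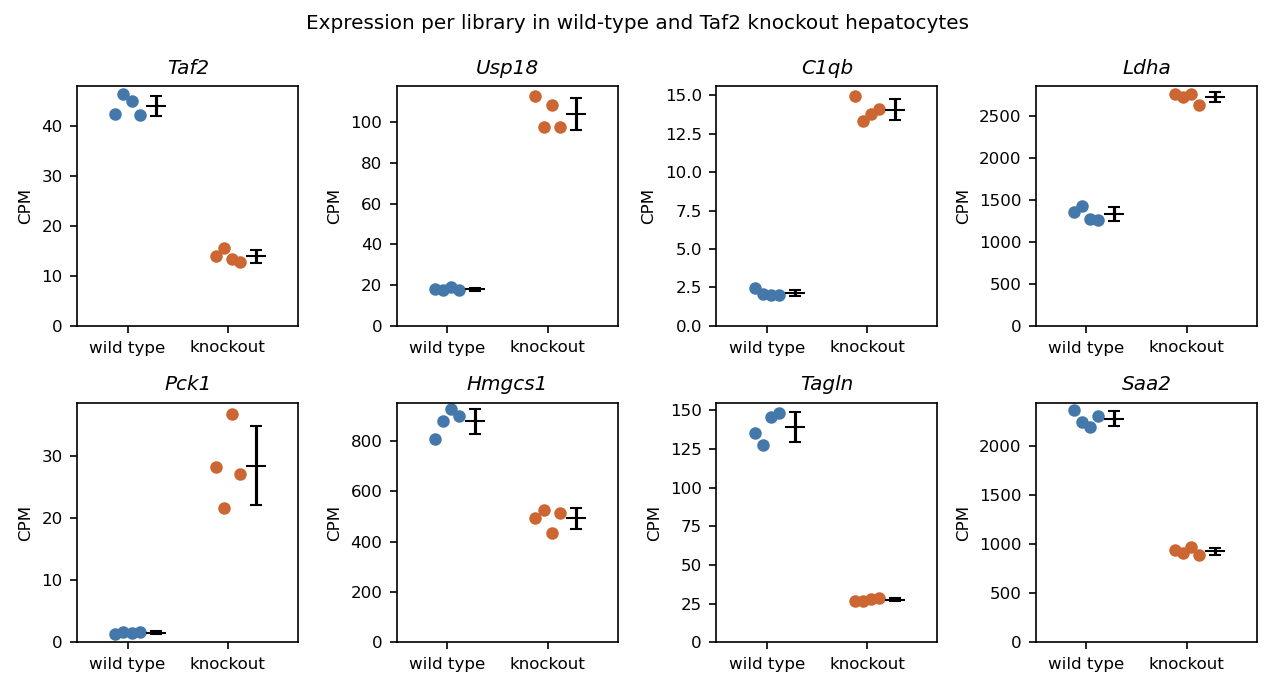
Normalised expression in CPM (vertical axes, each starting at 0) of 8 genes in each library of wild-type (blue) and Taf2 knockout (orange) hepatocytes, with the mean and SD of 4 libraries in black. Taf2 lies at 44.04 ± 2.05 CPM in the wild type and 13.9 ± 1.26 CPM in the knockout, and for every gene shown the 4 knockout libraries lie apart from the 4 wild-type libraries.

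Gene lists fixed in advance were then compared. Their members' calls use p-values adjusted over all genes tested, and counts adjusted over the list alone were the same except where a further pair is given. In the interferon-stimulated list, 39 of 41 tested genes rose and 2 fell, with a median log2 fold change of 1.86 (camera adjusted p = 2.78e-16, and adjusted p = 0.168 with an estimated correlation). Usp18, a negative regulator of interferon signalling, rose from 18.1 ± 0.744 to 104 ± 7.75 CPM, the transcription factor Irf7 from 17.2 ± 1.59 to 90.2 ± 7.64 CPM, and the antiviral gene Rsad2 from 7.26 ± 0.437 to 63.9 ± 7.99 CPM. Bst2, the most abundant member, rose from 99.02 ± 1.63 to 196 ± 8.11 CPM. The genes that fell were the chemokine gene Cxcl9 (log2 fold change -0.57, SE 0.072) and Ifit2 (-0.74, SE 0.11). Antigen presentation genes moved the same way, with 14 of 17 higher and 0 lower (median 0.63; camera adjusted p = 4.98e-06, and adjusted p = 0.119 with an estimated correlation). Tap1, a subunit of the peptide transporter, rose from 17.2 ± 0.836 to 42.1 ± 2.78 CPM. The class I genes H2-Q4, H2-Q7 and H2-K1 rose by 1.16, 1.39 and 0.34, with the reservation that reads are shared among class I genes. Macrophage, endothelial and stellate cell markers, described next, were higher in the same knockout libraries.

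**Figure D3:**
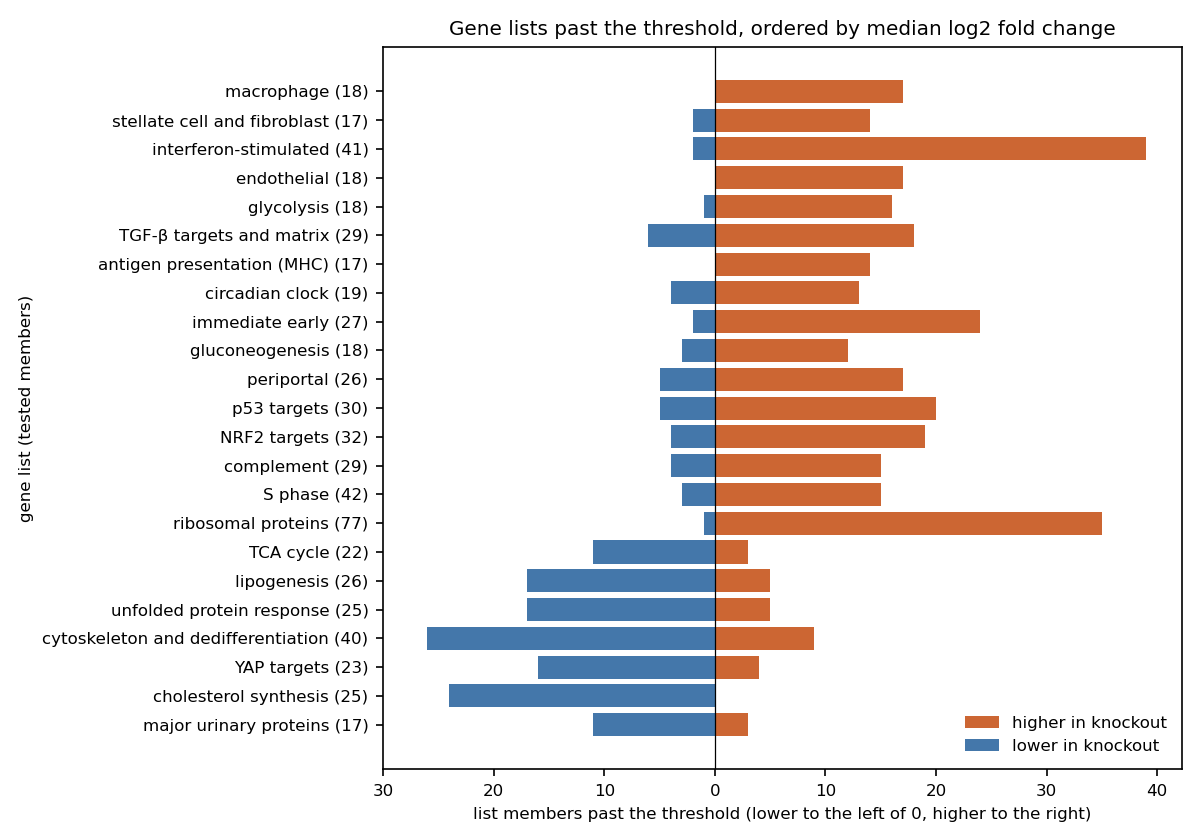
Number of members of each gene list that were higher (orange, to the right of 0) or lower (blue, to the left of 0) in Taf2 knockout hepatocytes at an edgeR adjusted p under 0.05, for the 23 lists past the camera threshold, ordered from the highest median log2 fold change (macrophage, 2.47) to the lowest (major urinary proteins, -0.88). The number of tested members stands in parentheses, and 39 of 41 interferon-stimulated genes were higher while 24 of 25 cholesterol synthesis genes were lower. With a correlation between genes estimated for each list, 2 of the 23 lists passed, macrophage and endothelial.

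Most markers of macrophages, endothelial cells and stellate cells were higher in the knockout, and most stood below 5 CPM in the wild type. Cholangiocyte markers, given further below, went the other way, with 7 of 9 lower and 2 higher. Of 18 macrophage markers 17 rose (median 2.47; camera adjusted p = 1.08e-10), and of 18 endothelial markers 17 rose (median 1.65; camera adjusted p = 2.43e-08). These were the 2 lists that also passed with an estimated correlation, each at adjusted p = 0.0282. The complement genes C1qa, C1qb and C1qc, which macrophages express, rose to between 10.4 and 14.1 CPM, C1qb from 2.14 ± 0.226 to 14.1 ± 0.675 CPM. Cd68, the most abundant macrophage marker, rose from 84.1 ± 11.97 to 173 ± 12.5 CPM, the endothelial adhesion gene Pecam1 from 6.93 ± 0.472 to 28.3 ± 1.72 CPM, and Cdh5 from 11.6 ± 0.724 to 35.1 ± 1.61 CPM. Among stellate cell and fibroblast markers 14 of 17 rose and 2 fell, or 15 and 2 adjusted over the list alone (median 2.18; camera adjusted p = 0.00017, and adjusted p = 0.0699 with an estimated correlation). The proteoglycan gene Dcn rose from 3.46 ± 0.527 to 26.4 ± 0.650 CPM and the pericyte gene Rgs5 from 0.710 ± 0.161 to 8.30 ± 0.495 CPM. The actin-binding protein gene Tagln and the smooth muscle actin gene Acta2 went the other way, Tagln from 139 ± 9.57 to 27.6 ± 1.01 CPM and Acta2 from 5.99 ± 0.987 to 2.37 ± 0.451 CPM. The 53 markers of these 3 lists summed to 528 ± 7.50 CPM in the wild type and 845 ± 19.6 CPM in the knockout. By list, summed CPM went from 203 to 401 for macrophage, from 87.5 to 216 for endothelial and from 238 to 229 for stellate markers, whose sum did not rise and includes Tagln. Only 3 macrophage, 6 endothelial and 4 stellate markers reached 5 CPM in the wild type.

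Further lists share members with these cell types. Of 29 TGF-β target and extracellular matrix genes 18 rose and 6 fell, or 19 and 6 adjusted over the list alone (median 0.75; camera adjusted p = 0.00374, and adjusted p = 0.48 with an estimated correlation). Without the members that the cell marker lists also hold, 27 remained and the camera adjusted p was 0.0137. Beside Dcn, the collagen gene Col6a1 rose from 0.400 ± 0.0978 to 6.72 ± 0.517 CPM, while Col4a1 fell from 253 ± 7.90 to 128 ± 3.51 CPM. Fn1, which encodes fibronectin and was the most abundant member, stood at 2577 ± 177 CPM in the wild type and 2760 ± 103 CPM in the knockout (edgeR adjusted p = 0.0571), and it passed in 10 of 16 alternatives, at values from 0.00631 to 0.231. In the complement list 15 of 29 genes rose and 4 fell (median 0.15; camera adjusted p = 0.0131, and adjusted p = 0.496 with an estimated correlation). The rises with the smallest p were those of C1qa, C1qb and C1qc, and without the members that the cell marker lists also hold the camera adjusted p was 0.101, the highest of its alternatives with fry and the estimated correlation set aside, which started at 0.00561. Masp1, a serine protease of the lectin pathway, fell from 57.2 ± 3.28 to 40.98 ± 1.90 CPM, and C3, the central complement component, was at 4965 ± 195 CPM in the wild type and 4897 ± 123 CPM in the knockout (edgeR adjusted p = 0.657).

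Glycolytic enzymes rose together in 16 of 18 cases (median 0.80; camera adjusted p = 2.4e-07, and adjusted p = 0.375 with an estimated correlation). The lactate dehydrogenase gene Ldha rose from 1333 ± 80.3 to 2723 ± 59.3 CPM, the phosphofructokinase gene Pfkl from 129 ± 8.66 to 291 ± 13.5 CPM, Pgk1 from 1397 ± 58.6 to 2701 ± 92.4 CPM, and Gapdh, the most abundant member, from 4161 ± 49.8 to 5662 ± 188 CPM. In 7 libraries part of the reads of Gapdh was shared with other genes. Pklr, the liver pyruvate kinase gene, fell from 272 ± 8.65 to 242 ± 15.1 CPM. In the list of gluconeogenesis and glycogen genes 12 of 18 rose and 3 fell, or 13 and 3 adjusted over the list alone (median 0.42; camera adjusted p = 0.00458, and adjusted p = 0.48 with an estimated correlation). Beside Pck1, the UDP-glucose pyrophosphorylase gene Ugp2 rose from 363 ± 29.8 to 717 ± 35.5 CPM and Ppp1r3b, which encodes a glycogen-targeting phosphatase subunit, from 18.6 ± 1.09 to 39.8 ± 2.85 CPM. Gckr, the glucokinase regulator gene, fell from 44.99 ± 2.30 to 31.5 ± 1.13 CPM. Enzymes of the TCA cycle and pyruvate dehydrogenase went down in 11 of 22 cases and up in 3, or 13 and 4 adjusted over the list alone (median -0.094; camera adjusted p = 0.044, and adjusted p = 0.48 with an estimated correlation). Ogdh, Pdha1 and Idh3a had log2 fold changes of -0.51 (SE 0.037), -0.43 (SE 0.034) and -0.42 (SE 0.039), and Mdh2 rose by 0.19 (SE 0.037). That list's call ended with upper-quartile scaling (camera adjusted p = 0.0572), a stricter low-count filter (0.0607) and a replicate block (0.0524). It also ended without wild-type replicate 1 (0.065) or 4 (0.052) and without knockout replicate 2 (0.0724) or 4 (0.0645), in a range from 0.0113 to 0.0724 with fry and the estimated correlation set aside.

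Enzymes of cholesterol synthesis and uptake fell in 24 of 25 cases and rose in 0 (median -0.55; camera adjusted p = 1.21e-09, and adjusted p = 0.375 with an estimated correlation). The remaining member, Tm7sf2, was at 54.8 ± 1.83 CPM in the wild type and 55.5 ± 2.01 CPM in the knockout (edgeR adjusted p = 0.67). Hmgcs1, the HMG-CoA synthase gene, fell from 878 ± 49.6 to 493 ± 40.6 CPM and Hsd17b7 from 123 ± 6.16 to 62.3 ± 4.80 CPM. Acat2 had a log2 fold change of -0.76 (SE 0.036), with part of its reads shared with a copy. Of 26 lipogenesis genes 17 fell and 5 rose (median -0.21; camera adjusted p = 0.0268, and adjusted p = 0.375 with an estimated correlation). The fatty acid elongase gene Elovl6 fell from 101 ± 6.64 to 51.3 ± 3.44 CPM and the acetyl-CoA synthetase gene Acss2 from 51.5 ± 1.63 to 33.2 ± 1.55 CPM, while Thrsp rose from 11.2 ± 0.723 to 21.9 ± 2.19 CPM. The desaturase genes Scd1 and Scd2, which share reads, had log2 fold changes of 0.23 (SE 0.036) and -0.88 (SE 0.074). Unfolded protein response genes fell in 17 of 25 cases and rose in 5 (median -0.22; camera adjusted p = 0.0205, and adjusted p = 0.375 with an estimated correlation). The endoplasmic reticulum chaperone genes Calr and Hspa5 had log2 fold changes of -0.43 (SE 0.038) and -0.14 (SE 0.037), and Dnajb9 rose by 0.70 (SE 0.049).

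Cytoskeletal and dedifferentiation genes, which cultured hepatocytes express strongly, fell in 26 of 40 cases and rose in 9 (median -0.23; camera adjusted p = 0.0035, and adjusted p = 0.496 with an estimated correlation). Beside Tagln, the calcium-binding protein gene S100a6 fell from 133 ± 12.9 to 38.7 ± 3.40 CPM and the calponin gene Cnn2 from 119 ± 5.24 to 53.6 ± 2.53 CPM. The keratin gene Krt8, the most abundant member, fell from 11760 ± 445 to 9784 ± 129.7 CPM, and the tubulin gene Tubb6 rose from 385 ± 1.97 to 606 ± 33.7 CPM. Targets of YAP, the transcriptional coactivator of the Hippo pathway, fell in 16 of 23 cases and rose in 4 (median -0.36; camera adjusted p = 0.00677, and adjusted p = 0.375 with an estimated correlation). Nt5e fell from 42.4 ± 2.61 to 13.4 ± 0.669 CPM, Amotl2 from 92.7 ± 1.81 to 58.02 ± 0.397 CPM, and Ctgf from 1232 ± 30.02 to 1017 ± 34.8 CPM. Axl, a receptor tyrosine kinase gene also expressed by macrophages, rose from 1.08 ± 0.332 to 7.25 ± 0.489 CPM.

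Immediate early genes rose in 24 of 27 cases and fell in 2 (median 0.61; camera adjusted p = 2.4e-07, and adjusted p = 0.233 with an estimated correlation). Fos rose from 6.21 ± 0.499 to 27.7 ± 2.09 CPM and Junb from 90.3 ± 3.84 to 168 ± 1.10 CPM; both encode subunits of the AP-1 transcription factor. Of 30 p53 targets 20 rose and 5 fell, or 21 and 5 adjusted over the list alone (median 0.27; camera adjusted p = 0.00319, and adjusted p = 0.334 with an estimated correlation). Ddit4, also known as an inhibitor of mTOR signalling, rose from 24.9 ± 1.77 to 89.96 ± 11.2 CPM, and Btg2, which is also an immediate early gene, from 109 ± 6.91 to 203 ± 3.59 CPM. The cell cycle inhibitor gene Cdkn1a rose from 391 ± 3.41 to 532 ± 24.2 CPM, and Perp fell from 194 ± 1.12 to 148 ± 4.20 CPM. Among NRF2 targets 19 of 32 rose and 4 fell (median 0.18; camera adjusted p = 0.00319, and adjusted p = 0.36 with an estimated correlation). Hmox1, the haem oxygenase gene, rose from 169 ± 7.91 to 772 ± 48.4 CPM, Ugdh from 284 ± 4.43 to 581 ± 26.8 CPM and G6pdx from 27.3 ± 0.943 to 62.7 ± 3.17 CPM. Gstm3 fell from 1326 ± 51.1 to 493 ± 23.01 CPM, with reads shared among glutathione S-transferase genes.

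Circadian clock genes rose in 13 of 19 cases and fell in 4, or 15 and 4 adjusted over the list alone (median 0.62; camera adjusted p = 0.00518, and adjusted p = 0.513 with an estimated correlation). Per2 rose from 8.10 ± 0.150 to 26.4 ± 2.28 CPM and Tef from 13.99 ± 0.453 to 27.3 ± 0.926 CPM, while Clock fell from 107 ± 4.61 to 82.1 ± 5.18 CPM. Of 42 S-phase genes 15 rose and 3 fell (median 0.12; camera adjusted p = 0.0476, and adjusted p = 0.48 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose from 10.5 ± 1.17 to 72.3 ± 10.7 CPM, the cyclin gene Ccne2 from 2.66 ± 0.418 to 9.73 ± 0.805 CPM and Pcna from 74.3 ± 1.53 to 107 ± 4.50 CPM, whereas E2f2 fell from 3.10 ± 0.459 to 1.246 ± 0.377 CPM. The S-phase call ended with no low-count filter (camera adjusted p = 0.0559) and upper-quartile scaling (0.0563). It ended as well without wild-type replicate 1 (0.0612), 2 (0.0746) or 3 (0.0571) and without knockout replicate 2 (0.0665) or 4 (0.0884), in a range from 0.0278 to 0.0884 with fry and the estimated correlation set aside. Ribosomal protein genes were higher in 35 of 77 cases and lower in 1, or 32 and 1 adjusted over the list alone, by small amounts (median 0.090; camera adjusted p = 0.00992, and adjusted p = 0.887 with an estimated correlation). Rpl35a rose by 0.29 (SE 0.048) and Rps21 fell by 0.20 on the log2 scale. Without wild-type replicate 2 or 3 the camera adjusted p of the ribosomal list was 0.0708 or 0.0635, in a range that started at 0.000912 with fry and the estimated correlation set aside, and fry did not pass it (0.158).

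Hepatocyte functions moved in both directions. Of 23 hepatocyte markers 14 rose and 5 fell, and the list did not pass (median 0.27; camera adjusted p = 0.0506). It passed with camera on limma-voom's log2 CPM (0.049) and with a stricter low-count filter (0.0486). It also passed without wild-type replicate 2 (0.0426) or knockout replicate 4 (0.0362), in a range up to 0.0741 apart from fry and the estimated correlation. Fry also passed it (0.000363), and the estimated correlation did not (0.589). Alb rose from 38040 ± 1777 to 55180 ± 3032 CPM, the tyrosine aminotransferase gene Tat from 52.3 ± 0.588 to 126 ± 17.6 CPM, and Cyp2e1 from 294 ± 18.3 to 539 ± 33.9 CPM. Cps1, which encodes the first enzyme of the urea cycle, fell from 694 ± 27.3 to 441 ± 35.2 CPM. Genes typical of periportal hepatocytes rose in 17 of 26 cases and fell in 5 (median 0.29; camera adjusted p = 0.00608, and adjusted p = 0.375 with an estimated correlation). The glutaminase gene Gls2 rose from 24.8 ± 0.725 to 65.5 ± 5.51 CPM and Sox9, which bile duct cells also express, from 31 ± 0.807 to 73.5 ± 3.05 CPM. Major urinary protein genes, a family of near-identical copies whose single values are uncertain, fell in 11 of 17 cases and rose in 3, or 12 and 4 adjusted over the list alone (median -0.88; camera adjusted p = 0.0151, and adjusted p = 0.496 with an estimated correlation). Mup15 fell from 1702 ± 80.01 to 602 ± 6.10 CPM and Mup20, the most abundant, rose from 5382 ± 263 to 8557 ± 329 CPM, and the family's summed level was 17460 CPM in the wild type and 17630 CPM in the knockout.

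Cytochrome P450 genes of xenobiotic metabolism changed in every case, 14 up and 16 down of 30, without passing as a list (median -0.21; camera adjusted p = 0.565). Cyp2b10 fell from 113 ± 13.3 to 22.9 ± 2.90 CPM, Cyp2c29 from 514 ± 11.4 to 284 ± 4.35 CPM and Cyp3a11, the most abundant, from 4317 ± 143 to 2913 ± 113 CPM. Cyp2a5 and Cyp2d9 had log2 fold changes of -1.31 (SE 0.037) and 0.78 (SE 0.040), both with reads shared among family members. Of 26 acute phase genes 15 fell and 10 rose (median -0.25; camera adjusted p = 0.199). The serum amyloid genes Saa1, Saa2 and Saa3 fell, with log2 fold changes of -1.04 (SE 0.039), -1.30 (SE 0.037) and -1.78 (SE 0.058). Reads are shared between Saa1 and Saa2, and in 5 libraries part of the reads of Saa3 was shared with other genes. The haemopexin gene Hpx fell from 8590 ± 199 to 7082 ± 237 CPM. Liver transcription factor genes fell in 12 of 21 cases and rose in 5 (median -0.18; camera adjusted p = 0.359). Nr1h4, the bile acid receptor gene, fell from 42.6 ± 1.23 to 18.2 ± 1.20 CPM, the oxysterol receptor gene Nr1h3 from 48.6 ± 2.01 to 28.99 ± 1.43 CPM and Foxa1 from 16.4 ± 1.72 to 11.1 ± 0.523 CPM, while Cebpb rose from 88.4 ± 4.81 to 141 ± 7.54 CPM. Hnf4a, the most abundant, was at 356 ± 8.02 CPM in the wild type and 366 ± 1.86 CPM in the knockout (edgeR adjusted p = 0.268).

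The other subunits of TFIID did not pass as a list, with 6 of 14 higher and 1 lower, or 5 and 1 adjusted over the list alone (median 0.087; camera adjusted p = 0.403). Taf5 rose from 3.76 ± 0.379 to 7.14 ± 0.745 CPM, Taf7 from 3.83 ± 0.569 to 5.44 ± 0.299 CPM and Taf9, which shares reads with another gene, from 62.9 ± 1.62 to 83.4 ± 5.86 CPM. Taf10, the most abundant, fell from 96.9 ± 4.08 to 81.7 ± 3.58 CPM. General transcription factors (7 higher and 4 lower of 21; 7 and 3 adjusted over the list alone), SAGA (2 higher and 5 lower of 16), RNA polymerase II subunits (2 higher and 2 lower of 13) and Mediator (10 higher and 7 lower of 32; 8 and 7 adjusted over the list alone) had camera adjusted p-values of 0.793, 0.636, 0.636 and 0.856.

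Further metabolic and secretory lists did not pass. Their counts were 15 higher and 17 lower of 35 for phase II conjugation (camera adjusted p = 0.636), 13 higher and 15 lower of 34 for fatty acid oxidation (0.793), and 12 higher and 8 lower of 23 for apolipoproteins (0.636). Urea cycle and amino acid genes had 17 higher and 15 lower of 43 (0.648), coagulation factors 12 higher and 9 lower of 25 (0.636), and subunits of respiratory complex I 8 higher and 7 lower of 37, or 8 and 4 adjusted over the list alone (0.636). Sex-biased growth hormone targets had 7 higher and 5 lower of 15 (0.525), and insulin-like growth factors and hepatokines 14 higher and 13 lower of 28 (0.648).

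Stress, growth and inflammation lists without a call were the integrated stress response (10 higher and 11 lower of 26; camera adjusted p = 0.952), heat shock (5 higher and 9 lower of 22; 0.758), apoptosis (12 higher and 8 lower of 32; 0.648) and NF-κB targets (8 higher and 10 lower of 27; 0.968). Mitotic genes had 3 higher and 5 lower of 30, or 1 and 4 adjusted over the list alone (0.724). Replication-dependent histone genes had 4 higher and 0 lower of 6, or 5 and 0 adjusted over the list alone (0.0603), and passed with no low-count filter at 0.0202, in a range that ended at 0.166 with fry and the estimated correlation set aside, and with fry at 0.00146. Proteasome genes had 4 higher and 7 lower of 31, or 4 and 6 adjusted over the list alone (0.816), and ribosome biogenesis genes 8 higher and 8 lower of 32, or 8 and 7 (0.975). Too few members were tested for a list test of T, B and NK cell markers (Ptprc, which rose by 2.11), neutrophil markers (Mmp8 and Hdc, which rose by 3.09 and 2.33) and erythroid markers (Alas2 and Bpgm, with log2 fold changes of -0.43 and -0.31). Genes of the mitochondrial genome were not analysed here. Median, mean and camera direction differed in sign for 8 lists, none of them past the threshold: general transcription factors, bile acid genes, fatty acid oxidation, apoptosis, the integrated stress response, heat shock, NF-κB targets and ribosome biogenesis.

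Of the 53 lists tested, 23 passed the camera threshold, 16 of them upward and 7 downward, and 2 passed with an estimated correlation. Genes whose libraries did not overlap between the genotypes numbered 6625 (54.7% of those tested, against 2.86% by chance). The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. All levels are relative to each library's total, so they do not show whether the amount of RNA per cell differed.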

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

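The tests on the common rise of the marker lists, on hepatocyte markers and on plating were chosen only after the result was seen. The tests on other splits, on the interferon list and on low-oxygen genes were set before their own results were seen. The low-oxygen genes were, however, chosen after the glycolysis result and after the rises of Vegfa, Adm, Ndrg1 and Egln3 had been seen.

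In 274 groups of 4 libraries, 1 library stood apart from the others in 18 by a gap that took most of the group's range, where chance gives about 13.7. In the wild type, replicate 2 had 2.33 CPM of Ptges (others 1.46 to 1.52) and 1249 CPM of Gstm3 (1349 to 1354). Replicate 3 had 84.6 CPM of Junb (91.6 to 93.0), 4991 CPM of Mup20 (5460 to 5554) and 18.95 CPM of Foxa1 (15.3 to 15.7). Wild-type replicate 4 had 1277 CPM of Ctgf (1214 to 1220), and replicate 1 had 407 CPM of Mdh2 (369.5 to 374). In the knockout, replicate 1 had 2.84 CPM of Mup17, where the others had 0, and 33.2 CPM of Gckr (30.9 to 31.0). Knockout replicate 2 had 3.05 CPM of Mup9 (2.29 to 2.37) and 1501 CPM of Rps2 (1673 to 1708). Replicate 3 had 78.1 CPM of Sox9 (71.5 to 72.5), 73.7 CPM of Gls2 (61.7 to 63.5), 10.9 CPM of Ccne2 (9.23 to 9.39) and 446 CPM of Calr (492 to 499). Knockout replicate 4 had 2563 CPM of Pgk1 (2735 to 2753), 95.1 CPM of Apoc2 (83.3 to 85.2) and 1053 CPM of Saa1 (1126 to 1138).

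The real split of the 8 libraries called 7447 genes, and the highest count among the other splits was 0. Of 35 splits into 4 and 4, 1 gave as many, the real one, the lowest share this design allows. Every other split puts libraries of both genotypes in each group, so the genotype difference widens the spread within groups and few calls follow. The test therefore cannot exclude a chance difference between cultures, because the labels do not say whether replicates came from separate animals.

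Markers of macrophages, endothelial cells and stellate cells were higher in the knockout, with medians of 2.47, 1.65 and 2.18, although the summed CPM of the stellate markers went from 238 to 229. Fewer reads on hepatocyte genes were argued against, since the hepatocyte markers had a median of 0.269 (bootstrap SE 0.1), although a small number of added cells would barely move them. A larger share of all such cells stays open: the range of the 3 medians was 0.818, with a permutation p = 0.0814 over 100000 resamples, which neither separates the lists nor shows that they moved alike. Cholangiocyte markers, with 7 of 9 lower, leave it open too, because 8 of them were already at 5 CPM or more in the wild type. A change in these cells or in marker expression by hepatocytes of the knockout may contribute as well, and no test here bears on either.

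Interferon-stimulated genes summed to 764 ± 14.4 CPM in the wild type and 1807 ± 85.7 CPM in the knockout. Reads shared between near-identical copies were argued against, since the 31 members with whole counts in all libraries had a median of 1.43 and 29 of them rose. Their list rose by 3.29 times as many CPM as the non-parenchymal markers did (2.99 to 3.6 over 16 pairs of libraries), a ratio that the fall of Tagln among the markers raises, above the bound of 2 set beforehand as excluding RNA brought by such cells. That bound assumed how abundant markers are in those cells, for which no profile was used here, and the list's median of 1.86 lies between the markers' 1.65 and 2.47, so the source of the RNA stays open. An interferon response of the knockout hepatocytes is a hypothesis that was not tested apart from these cells.

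Glycolysis genes rose with a median of 0.80, in 16 of 18 cases. Of 17 low-oxygen response genes outside the genes already examined, 16 rose with a median of 1.08 (one-sided Fisher's exact p = 5.75e-08 against all tested genes). A low-oxygen response in the knockout cultures would give such rises. Rises of Vegfa, Adm, Ndrg1 and Egln3, which respond to low oxygen too, had been seen when the 17 were chosen. The p-value is therefore not independent support for that response. Fisher's test also counts each gene as independent, and genes of a shared response may vary together, so the p-value may be too small. Bnip3 rose from 215 ± 36.5 to 933 ± 72.2 CPM, Egln1 from 74.1 ± 1.63 to 194 ± 21.6 CPM and Pdk1 from 65.97 ± 7.49 to 199 ± 15.8 CPM, and Pfkfb4 was at 0.968 ± 0.0957 CPM in the wild type and 0.955 ± 0.299 CPM in the knockout (edgeR adjusted p = 0.934). A difference in plating or culture conditions between the genotypes, such as cell density, could give the same values and cannot be told apart from the genotype, because 0 samples carry a label for plating, litter, batch or date. The genotype itself remains among the open explanations.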

How the results depend on the processing

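The estimated-correlation, fry, scaling, filter, replicate block, thinning and leave-one-out tests were planned, and the removal of shared marker genes was chosen only after the result was seen. Taf2 was lower in all 16 alternatives, with log2 fold changes from -1.71 to -1.62. Across the other tests and scalings, with the size threshold set aside, higher genes numbered 3479 to 4023 and lower genes 3411 to 3981. The highest share of higher genes among calls was 53.8%, with upper-quartile scaling (4001 and 3435), against 49.2%. Thinning to equal depth gave 3652 and 3578 calls, so depth differences changed the counts little. Leaving out each library in turn gave 3491 to 3626 higher and 3483 to 3663 lower genes, and 6231 of the 7447 calls (83.7%) were kept in all 8 of those fits. DESeq2 also called 6864 of them. A log2 change of at least 1 left 836 higher and 315 lower, by its own construction.

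The labels share replicate numbers between genotypes, but the same-numbered libraries had correlations of deviations from -0.069 to 0.011, and 0 of 4 numbers had both libraries correlating best with each other. With a replicate block 3666 genes were higher and 3771 lower, 22 lists passed, and the TCA cycle list was at 0.0524.

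Of the 23 lists, 2 passed with an estimated correlation, while fry, which does not compare a list with other genes, passed 39 but not the ribosomal proteins. Between 21 and 24 passed in all other alternatives. The calls that ended were TCA cycle, S phase, ribosomal proteins and complement, and hepatocyte markers and replication histones were gained, each as given with its result. Camera's direction turned only in lists that never passed. With upper-quartile scaling the median was -1.6e-05 for the proteasome. With no low-count filter medians were -0.0071 for Mediator, -0.034 for NF-κB targets and -0.020 for ribosome biogenesis. For NF-κB targets (median -0.025) fry's own direction was upward, against camera's downward one. Without 1 library, camera's direction turned for the proteasome (medians from -0.043 to -0.013 over the 8 fits, turned without wild-type replicate 4 or knockout replicate 2) and for ribosome biogenesis (from -0.022 to 0.018, turned without wild-type replicate 2, 3 or 4). C3 was at 0.0040 with upper-quartile scaling. The cause was not tested for any of these. Of single named genes, Mup17 and Atp6v0c-ps2 were not called by DESeq2 and had larger falls with limma-voom. Fn1 passed in 10 of 16 alternatives (adjusted p from 0.00631 to 0.231), Rps2 in 1 (without knockout replicate 2, 0.0301, up to 0.61) and Gstp1 in 1 (without wild-type replicate 4, 0.0487, up to 0.49).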

Other observations

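The test of the region around Taf2 was chosen only after the result was seen, and the serum response factor targets were chosen after the fall of the actin genes. The single genes in this part were also named after their values were seen.

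Pericentral, bile acid and cholangiocyte lists did not pass with camera. Of 22 pericentral genes 9 rose and 9 fell, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.636). The retinaldehyde dehydrogenase gene Aldh1a1 fell from 950.2 ± 46.3 to 359 ± 34.7 CPM, Lect2 from 52.3 ± 4.16 to 15.9 ± 0.939 CPM and Cyp1a2 from 169 ± 7.68 to 94.4 ± 4.56 CPM, while Cyp2e1 rose. Of 22 bile acid genes 9 rose and 7 fell (camera adjusted p = 0.952). Baat, which conjugates bile acids, fell from 20.8 ± 0.637 to 7.53 ± 1.24 CPM and the hydroxylase gene Cyp7b1 from 50.9 ± 2.23 to 22.6 ± 2.08 CPM, while the uptake transporter gene Slco1b2 rose from 11.3 ± 1.36 to 25.4 ± 2.05 CPM. Cholangiocyte markers fell in 7 of 9 cases and rose in 2 (camera adjusted p = 0.128). Krt19 fell from 19.5 ± 0.86 to 13.8 ± 1.62 CPM and Sox9 rose.

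Cyclins and cyclin-dependent kinase inhibitors of the G1 phase rose in 9 of 16 cases and fell in 2 (camera adjusted p = 0.0701). The cyclin genes Ccnd1 and Ccnd2 rose from 6.67 ± 0.486 to 12.8 ± 1.6 CPM and from 1.52 ± 0.194 to 5.56 ± 0.974 CPM, and the inhibitor gene Cdkn1b from 18.5 ± 1.08 to 29.9 ± 1.93 CPM. Oncofetal genes had 5 higher and 6 lower of 14 (camera adjusted p = 0.636), with the alpha-fetoprotein gene Afp lower, from 7.39 ± 0.601 to 4.98 ± 0.715 CPM. Outside any list, Vegfa rose from 93.4 ± 6.79 to 312 ± 25.02 CPM, Adm from 14.1 ± 2.59 to 104 ± 12.7 CPM, Ndrg1 from 75.6 ± 3.81 to 478 ± 57.7 CPM and Egln3 from 37.04 ± 4.89 to 256 ± 29.8 CPM. These rises had been seen before the low-oxygen genes tested above were chosen.

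Muscle-type actin and actin-binding genes were lower in the knockout, Actc1 from 83.7 ± 4.80 to 16.9 ± 2.35 CPM, Acta1 from 103 ± 5.46 to 41.3 ± 1.29 CPM, Tpm2 from 278 ± 10.03 to 91.8 ± 4.76 CPM and Myl9 from 17.9 ± 0.820 to 4.57 ± 0.635 CPM. A hypothesis is that targets of serum response factor, which drives such genes, may be less active. Of 14 further targets 8 fell (one-sided Fisher's exact p = 0.0396 against all tested genes), with a median of -0.19. The 14 include Acta2, whose fall is given above with the stellate cell markers. The count without Acta2 was not tested, so the p-value is not independent of genes already seen. This test too counts each gene as independent, so its p-value may be too small. Srf itself, Vcl, Zyx, Pdlim7 and Filip1l rose, by 0.54, 0.26, 0.15, 0.18 and 0.14, so the targets did not move as a unit.

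Deptor, which lies beside Taf2 on chromosome 15 (55112317 to 55259273), fell from 63.7 ± 2.83 to 30.2 ± 2.69 CPM. Of 7 tested genes within 1 Mb of Taf2, 4 fell (one-sided Fisher's exact p = 0.142). Deptor, whose fall led to the test, is itself counted among the 7 and among the 4. The others that fell were Mal2, Sntb1 and Enpp2, with log2 fold changes of -0.49, -0.54 and -0.21, while Col14a1 rose by 3.11. With 7 genes, each counted as independent, this test cannot tell whether the region as a whole changed.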
